A study of Mus musculus with 2 samples.

How the data were processed

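Cells expressing yellow fluorescent protein from the Cx3cr1 locus were sorted from dissociated mouse spinal cords of the C57BL/6J background and made into 10x Chromium 3′ libraries, per the labels' protocols. The labels give 23500 sorted and 4500 recovered cells for the wild-type, vehicle library and 22800 and 2600 for the Runx1 knock-out, tamoxifen library. There was 1 library per group, and the number of animals pooled into each is not given in the sources used here. Tamoxifen was given at 1 mg per day. Tissue for both libraries was digested with collagenase at 2 mg/ml for 30 min at 37 °C, per the labels. The deposited values were raw UMI counts per gene and barcode in filtered matrices. STAR, Cell Ranger 2.0.1 and Seurat 2.1.0 and the mm10 and GRCm38.p5 builds are named per the submitters' processing notes, with no role or order; which barcodes were kept, and how, is not given in the sources used here. The deposited lists of barcodes and of genes carry other, non-numeric content. Gene positions are from GENCODE M21 on GRCm38, in which 27645 of the 27998 gene identifiers were found.

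The groups, gene lists, markers, named-gene rule and first set of alternatives were fixed before the data were examined. Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 8 barcodes of the library labelled knock-out and none of the wild-type library. Both libraries were clustered together, without batch correction, on log-normalised counts of 2000 variable genes, without Runx1 and the sex-linked genes, reduced to 30 principal components. Leiden clustering (leidenalg 0.10.2) used 15 nearest neighbours and resolution 0.5. No doublet caller was used for the main values; Scrublet (in scanpy 1.11.5) served as an alternative that removed the 168 and 54 highest-scoring cells, at 0.8% per 1000 barcodes.

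Clusters were named from 21 fixed marker lists. The scoring was set after the clusters were seen, because clusters also held RNA of the markers of other types. A marker counted when it had at least 20 CPM and lay above the middle of its range over clusters. A cluster took the type with at least 2 counted markers among its top 10 genes by fold (pseudocount 20 CPM), or else the type with the largest share of counted markers and no rival at 60% of that share, and needed at least 3 counted markers, 50% of the type's list and no other type with more counted markers in the top 10. Clusters 4, 6 and 10 stayed unnamed under this rule.

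UMI counts were summed over the cells of a class and library and divided by the sum over all genes of the same cells, giving CPM. The log2 ratio is the library labelled knock-out over the library labelled wild type, with the exact conditional binomial interval at 95%. CPM carry exact Poisson intervals and shares exact Clopper-Pearson intervals, and a count of 0 was put at 3 counts. UMIs are molecules rather than reads, and the intervals leave out all variation between animals and libraries. Genes entered at 20 CPM in at least 1 library. Named genes were Runx1, the 12 highest and 12 lowest ratios whose interval excluded equality, without sex-linked and unnamed genes, up to 4 members of each list with the largest absolute ratio, a fixed set (Fos, Egr1, Il1b, Tnf, P2ry12, Tmem119, Cx3cr1, Apoe, Cd74, Spi1 and Csf1r) and the sex-linked genes.

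The 30 gene lists were described by the median log2 ratio of their measured members, for the 28 with at least 3 of them, and by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe the 2 libraries and are no test. For scores per cell, cells were thinned to 1500 UMIs without replacement; no cell fell below that number. On simulated data for this comparison, with 5501 genes in the step and 200 of them changed, intervals held the true ratio for 98% of genes set to 0.25 times, 98% at 0.5 times, 100% at 2 times and 96% at 4 times the level, 50 genes each, and for 95.2% of 5281 unchanged genes. A planted list of 20 genes shifted by 0.5 on the log2 scale lay at percentile 100, and 8 of 100 unchanged lists lay outside the middle 95%. The simulated counts were Poisson draws around the pooled means of both libraries, which is the model that the intervals assume. They held no further variation between cells or libraries and no added free RNA, so these results check the calculation only.

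Alternatives changed the scaling, the genes in the total, the weight per cell, the depth, the cell filter, doublets, the class, the minimum CPM and the clustering. A further 5 were added after the data were seen. List medians were taken over members that were microglia-enriched, at 2 times the level of endothelial-like and pericyte-like cells, in either library. An earlier form judged each gene only in the library where it was higher, so the direction of the ratio entered the choice of members; its values are given only among the alternatives. Background was taken out by subtracting the library-wide profile at the share that puts endothelial markers in microglia-like cells, or microglia markers in endothelial-like and pericyte-like cells, at 0, with levels under 5 CPM set to 5, so that a ratio with 1 library at that level is set by the minimum. The share is an upper estimate only if free RNA has the library-wide profile, and such a ratio is no bound. Microglial genes lose their ratio in the latter classes by this construction. Microglia-like cells were also taken from clusters at resolution 1.0, and from barcodes at or above the lowest wild-type UMI total. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.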

Results

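Single-cell RNA libraries were made from the mouse spinal cord to ask what loss of the transcription factor Runx1 does to microglia, the resident macrophages of the central nervous system. The mice carried a tamoxifen-inducible Cre recombinase and yellow fluorescent protein at Cx3cr1, a chemokine receptor gene of microglia and other mononuclear phagocytes, together with a floxed Runx1 gene. A library of vehicle-injected mice labelled wild type was set against a library of tamoxifen-injected mice labelled Runx1 knock-out, so tamoxifen and the knock-out cannot be told apart, and the number of animals per library is not given in the labels. Fluorescent cells were sorted 4 weeks after the first of 5 daily injections. With 1 library per group there was no replicate check, no test was possible, and every interval is a 95% interval that covers counting error only. The files held 4582 barcodes and 37446978 UMIs for the wild-type library and 2604 barcodes and 13075939 UMIs for the library labelled knock-out, beside 4500 and 2600 recovered cells in the labels. The median barcode had 6376 UMIs in the wild-type library and 3715.5 in the other, and the lowest totals were 2972 and 1780 UMIs.

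Runx1, the targeted gene, was not lower in the library labelled knock-out. In microglia-like cells it had 1445 UMIs or 92.9 CPM (88.1 to 97.8) in the wild-type library and 1126 UMIs or 181 CPM (171 to 192) in the library labelled knock-out, a 1.95-fold higher level and a log2 ratio of 0.96 (0.85 to 1.08). With every cell thinned to 1500 UMIs, 13.3% of 2158 wild-type microglia-like cells (11.9 to 14.8) and 22.6% of 1361 cells of the other library (20.4 to 24.9) held a Runx1 UMI. Unthinned shares were 43.4% and 49.6%, at median depths of 5520.5 and 3477 UMIs. Endothelial-like cells, which gave the background level, held a thinned Runx1 UMI in 3.39% (2.54 to 4.42) and 2.63% (1.66 to 3.96) of cells, at median depths of 5875 and 3619 UMIs. Runx1 lies at chromosome 16, positions 92601466 to 92826149 on the minus strand of GRCm38 (ENSMUSG00000022952). The tags come from the 3′ end of transcripts, the labels do not name the deleted part of the gene, and a tag outside that part checks nothing. These tags thus neither bear out nor contradict the label. Each direction below compares the library labelled knock-out with the library labelled wild type and does not stand for loss of Runx1.

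The sorted cells were not microglia alone. Microglia-like cells were 47.1% (45.6 to 48.6) of the 4582 wild-type cells and 52.4% (50.5 to 54.4) of the 2596 filtered cells labelled knock-out, and endothelial-like cells, which line vessels, were 33.5% (32.2 to 34.9) and 32.2% (30.4 to 34.0). Pericyte or smooth muscle-like cells numbered 180 and 124, erythrocyte-like cells 54 and 61, ependymal-like cells 19 and 28, border-associated macrophage-like cells 21 and 7, oligodendrocyte-like cells 18 and 8, fibroblast or meningeal-like cells 11 and 11, and neutrophil-like cells 7 and 1. A further 578 and 160 cells stayed unnamed. Of these, cluster 4 held microglial and endothelial markers together in 421 and 94 cells (9.19% and 3.62%) with a pooled median of 11488 UMIs, and 34.8% of its cells were among the highest doublet scores. Cluster 6 had Gkn3, Vegfc and Bmx beside endothelial markers in 136 and 50 cells (2.97% and 1.93%). Cluster 10, with 21 and 16 cells (0.458% and 0.616%), had 10 cycling markers, a share of 0.833 of the microglia markers and a share of 0.667 of the natural killer cell markers. When each library was clustered on its own, a cluster of 12 cells labelled knock-out had 10 cycling and 11 microglia markers, and Gzma and Nkg7 were among the top 10 genes of a cluster of 32 wild-type cells. The fluorescence gate, the different lowest UMI totals and the unequal depth can each set these shares. Different clusters held the same class in the 2 libraries: microglia-like cells of the wild-type library lay in cluster 0, and 1346 of the 1361 cells labelled knock-out lay in cluster 2. Endothelial-like cells lay mostly in cluster 1 for the wild-type library and in cluster 3 for the other.

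Microglial and endothelial RNA was present in every named class, and in microglia-like cells the endothelial, pericyte and erythrocyte markers were all higher in the wild-type library. The 12 microglia markers made up 18767 CPM of wild-type microglia-like cells and still 8315 CPM (8262 to 8368) of wild-type endothelial-like cells, against 21971 and 5413 CPM (5342 to 5485) in the library labelled knock-out. The 9 endothelial markers made up 6732 CPM (6691 to 6772) of wild-type microglia-like cells and 2267 CPM (2230 to 2305) of those labelled knock-out. Oligodendrocyte-like and ependymal-like cells showed the same order, with 5964 and 8526 CPM of endothelial markers in the wild-type library and 1803 and 2948 CPM in the other. Other pairs ran differently. Endothelial markers were at 14250 and 14267 CPM in pericyte-like cells of the wild-type library and the library labelled knock-out. They were at 13126 and 12952 CPM in erythrocyte-like cells and at 15242 and 15044 CPM in fibroblast or meningeal-like cells. Erythrocyte markers were higher in the library labelled knock-out in endothelial-like (5492 and 7844 CPM), pericyte-like (4115 and 22150 CPM) and ependymal-like cells (7022 and 20622 CPM). Where all endothelial marker RNA in microglia-like cells is counted as free RNA with the make-up of the whole library, it amounts to at most 50.4% of their UMIs in the wild-type library and 20.7% in the library labelled knock-out.

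**Figure D1:**
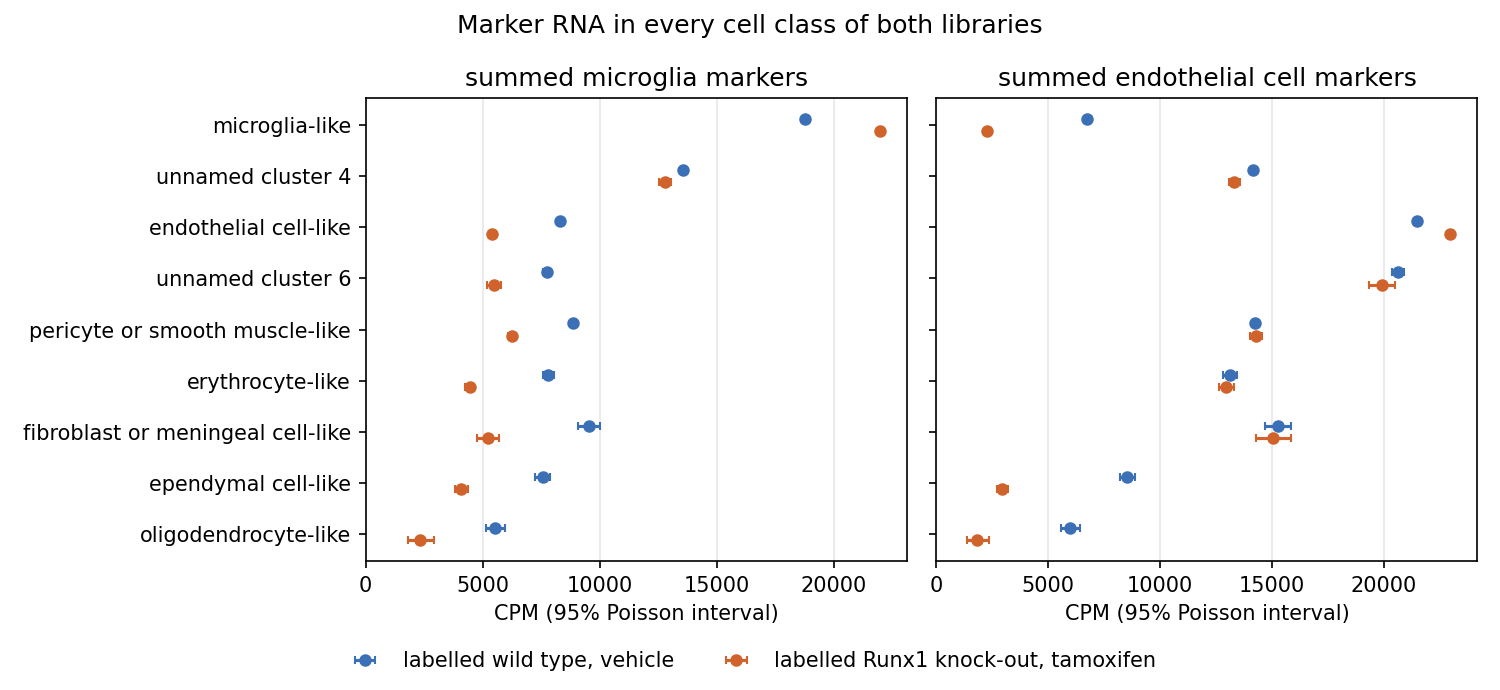
Summed microglia markers (left) and endothelial markers (right) in CPM on linear axes from 0, per cell class and library, with 95% Poisson intervals. Blue points are the library labelled wild type and orange points the library labelled Runx1 knock-out; endothelial markers lie at 6732 CPM and 2267 CPM in microglia-like cells.

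Cfp, Vps8, Cebpb and Marcksl1 were among the genes with the highest ratios in microglia-like cells. Among 5742 genes with at least 20 CPM in 1 library or both, Cfp, which encodes properdin, the positive regulator of the alternative complement pathway, went from 1.478 to 224 CPM (log2 ratio 7.24, 6.65 to 7.91). Vps8, a subunit of the endosomal CORVET tethering complex, went from 11.6 to 367 CPM (4.98, 4.76 to 5.21). Cebpb, a transcription factor of macrophage activation, went from 218 to 1132 CPM (2.37, 2.31 to 2.43), a 5.18-fold difference, and Marcksl1, an actin-regulating protein kinase C substrate, from 125 to 634 CPM (2.34, 2.26 to 2.42). The immune receptor gene Cd300lf and the chemokine gene Ccl24 had log2 ratios of 3.96 and 2.38. The remaining highest values were those of Dmpk (3.89), AB124611 (3.72), Eva1a (1.94), Dmwd (1.93), Whrn (1.93) and Actn1 (1.89). With the estimated background taken out, an alternative added after the data were seen, Vps8 was at 5.01. The wild-type levels of Cfp, Cd300lf, Dmpk, Dmwd and Actn1 were then at the 5 CPM minimum, which set their log2 ratios at 5.63, 3.08, 2.43, 2.29 and 3.53. The share taken out is an upper estimate only if free RNA has the make-up of the whole library. Ratios set by that minimum are therefore neither estimates nor bounds. The middle of all genes lay close to 0, with a median log2 ratio of -0.04. Cfp lies at chromosome X, positions 20925454 to 20931555, Vps8 at chromosome 16, positions 21423118 to 21644680, and Cebpb at chromosome 2, positions 167688915 to 167690418.

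The lowest ratios belonged to genes of several cell types. The neutrophil genes S100a8 and S100a9 went from 78.5 to 2.41 CPM and from 35.2 to 2.89 CPM, and S100a8 was lower in endothelial-like cells too, with a log2 ratio of -4.91 there against -5.03 in microglia-like cells. Summed neutrophil markers were at 161, 151, 159 and 160 CPM in wild-type microglia-like, endothelial-like, pericyte-like and ependymal-like cells. In the library labelled knock-out they were at 10.3, 8.53, 11.3 and 9.48 CPM, so this difference was not particular to microglia-like cells. Lyz2, which encodes lysozyme, went from 579 to 106 CPM (-2.44, -2.56 to -2.33). Rapsn, Ttll7, Cpe, Scgb3a1, Gkn3, Rab13, Gsta4, Hmcn1 and Tagln followed, with log2 ratios from -2.70 for Rapsn to -2.08 for Tagln, the smooth muscle gene transgelin. Most had higher levels in other classes. In endothelial-like cells Gsta4 was at 593 and 519 CPM, Cpe at 373 and 283 CPM and Hmcn1 at 221 and 282 CPM. Pericyte-like cells held 421 and 538 CPM of Gkn3 and 787 and 911 CPM of Tagln. Endothelial markers were lower in the same microglia-like cells too, as given above. Once the background was taken out, Lyz2 was at -2.74, and S100a9, Ttll7, Hmcn1 and Tagln were at or below 5 CPM in both libraries and had no ratio left. The other 7 were at or below 5 CPM in the library labelled knock-out alone, and that minimum set their values at -1.21 for S100a8, -1.37 for Cpe, -1.07 for Rab13, -0.92 for Scgb3a1, -2.85 for Gsta4, -2.51 for Gkn3 and -2.42 for Rapsn. Rapsn and Lyz2 alone among the 12 lowest were microglia-enriched, meaning at least 2 times the level of endothelial-like and of pericyte-like cells in either library, a rule added after the values were seen. The next lowest microglia-enriched genes were Olfml3, a microglial matrix gene that went from 1116 to 305 CPM (-1.87, -1.94 to -1.80), Ccl5 (-1.75), Tspan32 (-1.70), Lgals3 (-1.31), Fabp5 (-1.30) and Serpinf1 (-1.15). Of the 833 microglia-enriched genes measured in microglia-like cells, 639 had a ratio above 0, and their median log2 ratio was 0.31; judged by wild-type levels alone, 348 of 454 were above 0.

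**Figure D2:**
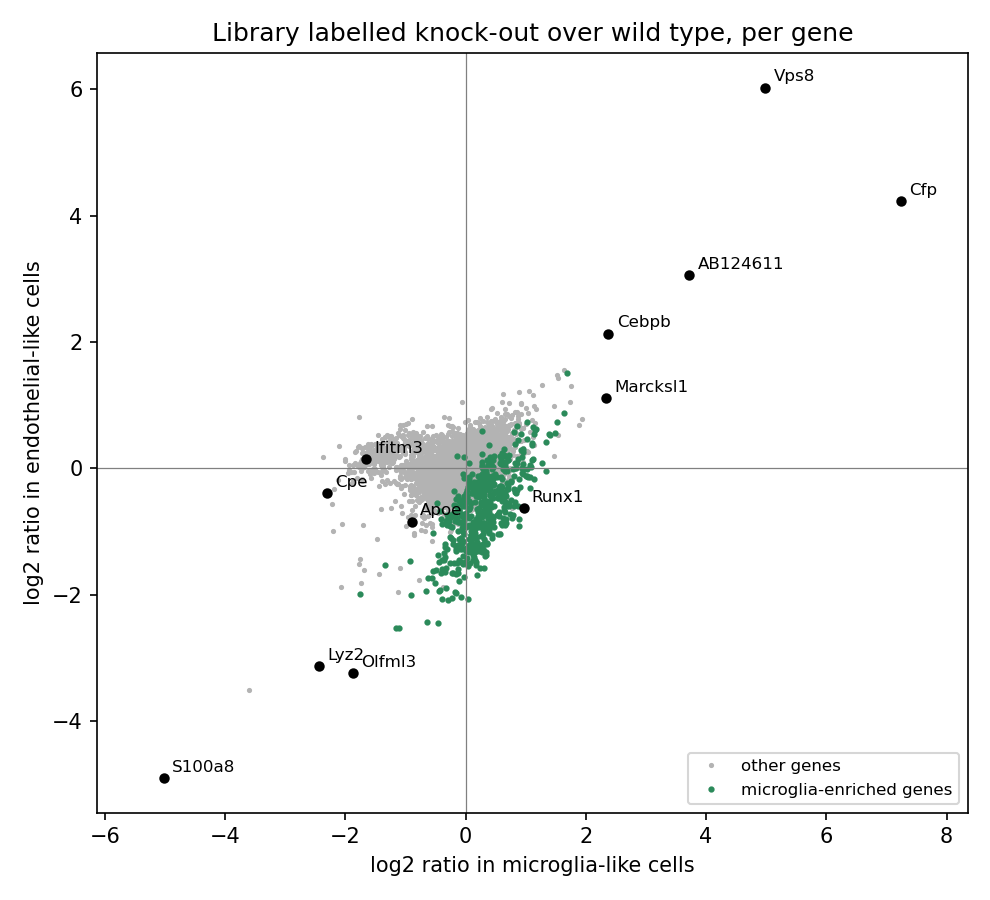
Log2 ratio of the library labelled knock-out over the library labelled wild type in microglia-like cells (horizontal) and in endothelial-like cells (vertical). Each point is a gene with at least 20 CPM in 1 library or both of each class, green points are genes microglia-enriched in either library, and named genes are in black; Vps8 lies at 4.98 and 6.03, and S100a8 at -5.03 and -4.91.

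Inflammatory and immediate early genes were higher together in microglia-like cells of the library labelled knock-out. The tissue was digested for 30 min at 37 °C. With 1 library per group, a response to that preparation cannot be told apart from a state in the animal. Of 29 measured inflammatory cytokines and NF-kB targets, 23 had a ratio above 0 and 6 below, with a median log2 ratio of 0.60 that lay above all 10000 random lists matched on expression. Tnfaip3, a feedback inhibitor of NF-kB, was at 1.63, Nfkb1 at 1.02, Icam1 at 0.95, and the cytokine genes Tnf and Il1b at 0.63 and 0.33, while the chemokine gene Ccl5 was at -1.75. Of 26 immediate early genes, 22 were above 0 and 4 below, with a median of 0.56, also above all random lists. Nr4a1 was at 1.47, Maff at 1.15, Socs3 at 1.14 and Zfp36 at 1.11, and the activity-induced transcription factors Fos and Egr1 were at 0.84 and 0.88. Microglia-enriched members of the 2 lists, 27 and 10 genes, had medians of 0.63 and 0.93, beside 0.31 for all microglia-enriched genes. The list medians without the background were 0.33, with 19 of 29 members above 0, and 0.44, and Tnf was at 0.33 and Il1b at 0.018. The heat shock list, another stress response, had 12 of 15 members above 0 and a median of 0.19 (percentile 93.5 of the random lists), with Hspa1b at 1.12 and Hspb1 at -1.17. In endothelial-like and pericyte-like cells the immediate early medians were 0.092 and 0.016, and the heat shock medians 0.017 and -0.010. Nr4a1 was still at 0.99 and 0.85 there. A response to preparation in microglia-like cells alone would leave the same values. The spread over cells differed from list to list. With cells thinned to 1500 UMIs, 36.4% (33.9 to 39.1) of microglia-like cells labelled knock-out lay above the wild-type 95th percentile of the immediate early list, and 13.7% (11.95 to 15.7) above that of the inflammatory list.

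Homeostatic genes, which mark surveying microglia, were mostly higher by a moderate amount. The list had 22 of 25 members above 0 and a median log2 ratio of 0.43, above all random lists, with medians of 6.67% and 8.33% of UMIs per thinned cell. P2ry12, a purinergic receptor of process movement, went from 1780 to 3229 CPM (0.86), Crybb1 was at 1.40 and Golm1 at 1.01, Cx3cr1 was at 0.43, and Tmem119 at 0.017 (-0.016 to 0.051), or -0.21 with the background taken out. Olfml3 and the protease inhibitor gene Serpine2 went the other way, at -1.87 and -1.05. The 20 microglia-enriched homeostatic members had a median of 0.43, at percentile 93.3 of random lists drawn from microglia-enriched genes, and with the estimated background taken out the list's median was 0.20. Microglial and myeloid transcription factors had 20 of 27 members above 0 and a median of 0.45 (percentile 100), with Cebpb at 2.37, Bach1 at 0.85, Sall1 at 0.79 and Spi1, which encodes PU.1, at 0.12, or -0.14 with the background taken out. All 4 measured genes with long-described Runx1-bound elements in blood cells lay above 0, with a median of 0.40 (percentile 96.4): Csf1r at 0.67, Cebpa at 0.46, Csf3r at 0.33 and Spi1 at 0.12. All 4 were microglia-enriched, and the list lay at percentile 67.1 of random microglia-enriched lists and at a median of 0.096, with 3 of 4 above 0, once the background was taken out. Chemokine and cytokine receptors had a median of 0.30 (percentile 99.9, 15 of 22 above 0), complement 0.32 (percentile 98.8, 7 of 10) and the TGF-beta pathway 0.29 (percentile 99.5, 13 of 17). Among random microglia-enriched lists the enriched members of the receptor, complement, TGF-beta and transcription factor lists lay at percentiles 80.7, 89.97, 78.9 and 84.5. The 4 medians without the background were 0.14, 0.20, 0.44 and 0.19. Toll-like receptors and adaptors had a median of 0.37 (percentile 99.7, 10 of 11), which was -0.035 over 13 members with the background taken out, and their enriched members lay at percentile 22.5.

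Genes of the disease-associated state, lysosomes and interferon response did not share that direction. Disease-associated genes had 13 of 20 members below 0 and a median of -0.17 (percentile 6.58), with Lyz2 at -2.44, Lgals3 at -1.31, Axl at -0.98 and the lipid carrier gene Apoe at -0.89 (4769 to 2566 CPM), and the 15 microglia-enriched members also had a median of -0.17. Lysosomal genes had a median of -0.052 (percentile 37.6), with 16 of 35 above 0. With the background taken out the disease-associated and lysosomal medians were -0.40 and -0.18. Type I interferon response genes had 19 of 21 members below 0 and a median of -0.71, below all random lists, with Ifitm3 at -1.66, Usp18 at -1.63, Slfn5 at -1.39 and Rtp4 at -1.16. Ifitm3 was at 1756 and 1946 CPM in endothelial-like cells against 797 and 253 CPM in microglia-like cells, and 2 of the 21 measured interferon members were microglia-enriched. Over all filtered cells the interferon median was 0.089, with Slfn5 at 0.063 and Rtp4 at 0.029, and with the background taken out it was -0.54 over 13 members, 11 of them below 0. Ifitm3 was then at -2.87, Usp18 and Rtp4 were at values set by the 5 CPM minimum in the library labelled knock-out (-0.86 and -0.66), and Slfn5 had no ratio left. Nuclear oxidative phosphorylation genes had 64 of 72 below 0 and a median of -0.36, and ribosomal protein genes 63 of 80 and a median of -0.17, at percentiles 0 and 0.01, and 0 members of either list were microglia-enriched. Background removal left the oxidative phosphorylation median at -0.23, with 56 of 72 below 0, and the ribosomal median at -0.24, with 68 of 80 below 0. Mitochondrially encoded genes had 11 of 12 above 0 and a median of 0.34 (percentile 99.2). The directions of these lists were not particular to microglia-like cells. In endothelial-like and pericyte-like cells the ribosomal medians were -0.23 and -0.33, and the oxidative phosphorylation medians -0.073 and -0.13. Mitochondrially encoded genes had medians of 0.13 and 0.12 in those classes. MHC class II genes had a median of 0.18 (percentile 87.0), with 6 of 7 above 0 and the invariant chain gene Cd74 at -0.17, and with the background taken out their median was -0.086, with 3 of 7 above 0.

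The other fixed lists in microglia-like cells had medians from -0.0041 to 0.33. Median log2 ratios were 0.081 for MHC class I presentation, with the peptide transporter gene Tap2 at 1.63, 0.19 for phagocytic receptors and engulfment, with Lrp1 at 1.06 and Axl at -0.98, and 0.16 for purinergic and ion channels. They were 0.33 for pain-related and trophic mediators, 0.099 for cytoskeleton and migration, 0.080 for apoptosis and p53 targets and 0.027 for glycolysis, in which the lactate exporter gene Slc16a3 was at 1.21 and the glucose transporter gene Slc2a1 at -0.79, or 2.47 with the background taken out, a value set by the 5 CPM minimum in the wild-type library. The Runx family and its partners had a median of 0.20, estrogen receptor and targets 0.24 over 5 measured members, cholesterol and lipid handling -0.0041 and S phase 0.0062 over 4 measured members. With the background taken out the medians of the pain-related, phagocytic, purinergic and Runx family lists were 0.12, 0.051, 0.00098 and 0.58. Those of the estrogen receptor, apoptosis, cytoskeleton, glycolysis and MHC class I lists were 0.53, 0.16, 0.16, 0.10 and 0.12. The cholesterol and S phase medians were then 0.0012 and -0.092. Of the list for the G2 and M phases only Hmgb2 reached 20 CPM, at 0.19. Of the sex-linked genes, Xist had 0 UMIs in both libraries, and the Y-linked Ddx3y and Eif2s3y had 53.02 and 49.6 CPM in the wild-type library and 54.3 and 51.4 CPM in the other. Kdm5d was at 6.43 and 7.07 CPM, Uty at 9.25 and 9.96 CPM, and Tsix at 0 and 1 UMI.

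**Figure D3:**
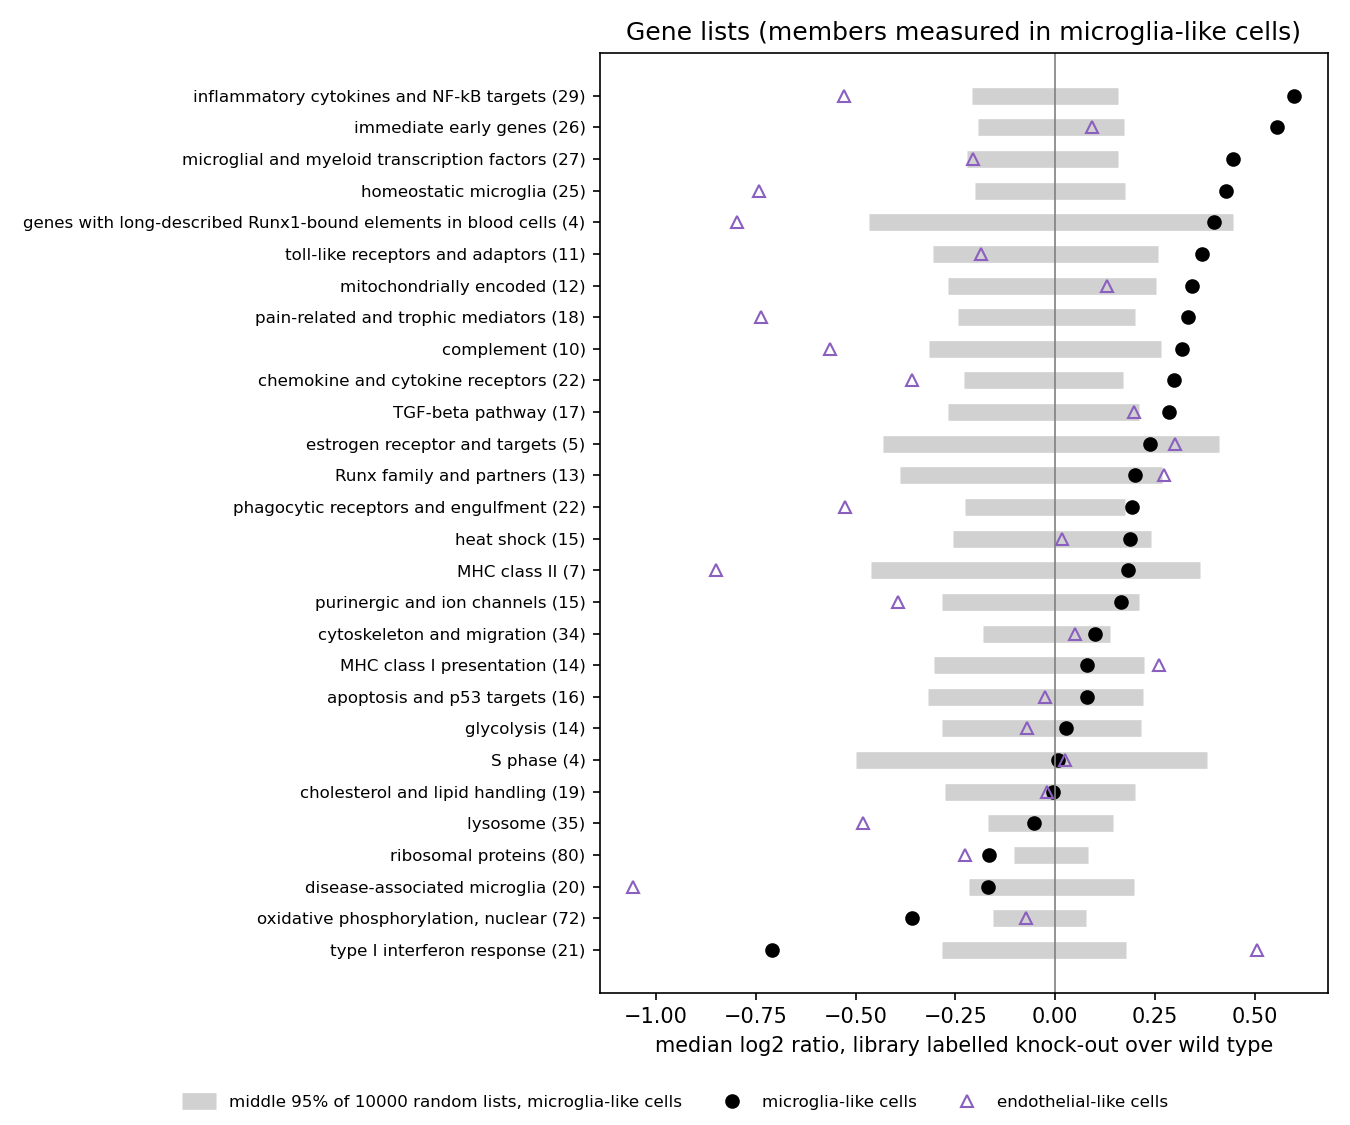
Median log2 ratio of each fixed gene list, library labelled knock-out over library labelled wild type, in microglia-like cells (black points) and endothelial-like cells (open triangles), with the number of members measured in microglia-like cells in brackets. Grey bars span the middle 95% of 10000 random lists in microglia-like cells; the interferon list lies at -0.71 and 0.51 in the 2 classes.

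Endothelial-like and pericyte-like cells, the other classes with at least 100 cells in each library, showed a partly different set of ratios. In endothelial-like cells Vps8 had a log2 ratio of 6.03 (5.81 to 6.26), from 15.2 to 994 CPM, and Runx1 went from 28.7 to 18.5 CPM (-0.63). Interferon response genes had a median of 0.51 there, above all random lists, and MHC class I presentation genes 0.26, while homeostatic, inflammatory and disease-associated microglial lists had medians of -0.74, -0.53 and -1.06, beside the lower microglial marker RNA given above. In pericyte or smooth muscle-like cells, which lay in clusters 5 and 8, Vps8 was at 6.08, Runx1 at -0.034 and the interferon list at 0.21. Cluster 5, with 146 and 106 cells, had a share of 0.889 of the endothelial markers beside 0.625 of the pericyte markers. This class is therefore not fully separate from endothelial-like cells. Among 5119 genes measured in all 3 classes, 12 were at least 2-fold higher in each class with an interval above 0 and 10 at least 2-fold lower. Vps8, Cfp, AB124611, Cebpb and Tap2 were among the higher genes, and S100a8, S100a9, Lyz2, Olfml3 and Ccl5 among the lower ones. With the background taken out at the share that puts microglia markers at 0 in endothelial-like and pericyte-like cells, Vps8, Tap2, Gm8797, mt-Atp8 and Gm9493 were still at least 2-fold higher in all 3 classes, and Gstp1 and Gm42418 had smallest log2 ratios of 0.93 and 0.80. Cfp, AB124611, Cebpb, S100a8, S100a9, Lyz2, Olfml3 and Ccl5 were then at or below 5 CPM in both libraries of these 2 classes, which left no ratio.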

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

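The comparison in this part was chosen after the result was seen, except that the gene list was fixed before the data were examined. The type I interferon response list lay on opposite sides of 0 in the 2 large classes of the same pair of libraries, with a median log2 ratio of -0.71 in microglia-like cells and 0.51 in endothelial-like cells. With the background taken out the medians were -0.54 over 13 measured members and 0.33 over 27, against 21 and 29 before. Of the 21, 2 were microglia-enriched, and Ifitm3, Usp18, Slfn5 and Rtp4 had higher levels in endothelial-like cells. Endothelial markers were also lower in microglia-like cells, at a median of -1.56. Free RNA therefore cannot be told apart from a change in microglia-like cells here. Homeostatic (0.43 and -0.74) and inflammatory (0.60 and -0.53) lists also lay on opposite sides, but with the background taken out their endothelial-like medians were 0.13 and 0.15, over 6 and 7 measured members against 25 and 28 before. Genes with Runx1-bound elements lay at 0.40 and -0.80, and with the background taken out 0 of them were measured in endothelial-like cells. Complement, phagocytic, apoptosis and glycolysis lists lay on opposite sides before and after that removal. Their medians after it were 0.20 and -0.23, 0.051 and -0.17, 0.16 and -0.17, and 0.10 and -0.044. For each of them, the median's interval before removal included 0 in at least 1 class. The difference between the classes was not tested, since there was 1 library per group.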

How the results depend on the processing

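The background removal, both rules for microglia-enriched members, the ratios at resolution 1.0 and the UMI minimum were added after the data were seen. Of 2036 alternative values for 181 results, 1730 stayed within the main interval, 293 left it, and 13 changed sign where the main interval excluded 0. A further 31, counted among the first 2 groups, changed sign where the main interval included 0, such as the disease-associated median over members enriched in the library where each is higher (0.11, against -0.17 over members enriched in either library, because the first rule lets direction enter the choice), and the MHC class II median (-0.086) and Tmem119 (-0.21) with the background removed. The Runx1 ratio of 0.96 stayed above 0 in the 11 alternatives run for it, at its lowest with the background removed (0.69) and at 0.77 over all filtered cells. Over all filtered cells, which mixes classes, the homeostatic median was 0.20 and that of immediate early genes 0.38, and the interferon median changed sign to 0.089. There Spi1 was at -0.085, Slfn5 at 0.063, Rtp4 at 0.029, Slc2a1 at 0.11, Tgfb2 at 0.037, Erg at 0.057, Vim at 0.26 and Igf1r at 0.12, each with the sign changed. With the background removed, the homeostatic median was 0.20, and Spi1 (-0.14), H2-DMb1 (-0.090), Slc2a1 (2.47, set by the 5 CPM minimum in the wild-type library) and the toll-like receptor list (-0.035) changed sign. Both rules for microglia-enriched members put the immediate early median at 0.93. The share of microglia-like cells in the wild-type library was 37.0% at resolution 1.0, where a cluster of 482 wild-type cells took a neutrophil name, and 49.1% without the highest doublet scores. That cluster also had a share of 0.583 of the microglia markers, and Spp1, Lpl and Lgals3 were among its top 10 genes beside neutrophil genes. In the library labelled knock-out the share of microglia-like cells was 49.8% under the stricter cell filter. The endothelial-like share in the wild-type library was 28.9% at resolution 1.0, 29.0% with each library clustered on its own, 29.1% with no cell filter and 30.0% with the stricter one. In the library labelled knock-out it was 27.4% at resolution 1.0 and 34.2% clustered on its own. The share of microglia-like cells with a Runx1 UMI depends on depth by construction, at 43.4% and 49.6% unthinned and 9.08% and 17.1% at 1000 UMIs. Other causes were not tested. No paired analysis was possible because there was 1 library per group. Depth limits genes near 20 CPM, and no alternative here measures the spread between animals.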

Other observations

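All tests in this part, with their thresholds, were chosen after the results or closely related values were seen. Among microglia-enriched genes outside the fixed lists, chosen after their values were seen, the chemerin receptor gene Cmklr1 went from 12.5 to 43.4 CPM (log2 ratio 1.80) and the organic anion transporter gene Slco4a1 from 8.997 to 29.6 CPM (1.72), while the interleukin 7 receptor gene Il7r went from 36.8 to 24.8 CPM (-0.57) and the niacin receptor gene Hcar2 from 74.3 to 47.6 CPM (-0.64). The latter 2 lay inside the middle 95% of all genes in microglia-like cells (-1.40 to 0.91). Among genes microglia-enriched in either library, disease-associated and lysosomal genes lay at the lower end of random lists of such genes (medians of -0.17 over 15 members and 0.0019 over 21, percentiles 0.03 and 0.79) and inflammatory genes at the upper end (0.63 over 27, percentile 99.99).

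Runx1 tags were higher, not lower, in microglia-like cells of the library labelled knock-out. More free RNA in the wild-type library would dilute all microglial genes alike. The lower limit of the Runx1 log2 ratio, 0.85, lay above the 0.23 of the summed microglia markers. Single markers did not move alike, with Olfml3 at -1.87, Tmem119 at 0.017, P2ry12 at 0.86 and Crybb1 at 1.40. Their sum is therefore no clear measure of dilution, and the comparison cannot decide whether free RNA plays a part. This test replaced an earlier one, the ratio with the background taken out (0.69), which rests on an assumed profile. With every cell thinned the ratio was 0.85 (0.63 to 1.08). CPM already divide by the UMIs of the same cells, so thinning could hardly change the ratio and decides nothing about depth. An exchange of labels cannot be told apart from a Runx1 transcript that keeps its 3′ end, because the ratio of 0.96 comes from tags that need not lie in the deleted part.

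Endothelial markers were lower in microglia-like cells of the library labelled knock-out, with a median log2 ratio of -1.56 and 9 of 9 below 0. Cell pairs under a shared barcode, if a minority, would leave most wild-type cells at the level of the other library, yet with cells thinned to 1500 UMIs the medians were 10 and 3 endothelial marker UMIs, and 99.0% of wild-type cells (98.5 to 99.4) lay above that median of 3, against 40.8% of cells labelled knock-out. This test replaced the share of cells with any such UMI, which was near its limit in both libraries (100% and 96.5%). Free RNA remains a candidate explanation, as the markers had a median of -1.19 (-1.58 to -0.50) over oligodendrocyte-like and ependymal-like cells, which are not endothelial. Border-associated macrophage-like cells held 7463 CPM of them in the wild-type library and 1964 CPM in the other. Free RNA leaves open why pericyte-like cells held 14250 and 14267 CPM. The same holds for erythrocyte-like (13126 and 12952 CPM) and fibroblast or meningeal-like cells (15242 and 15044 CPM).

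Vps8 was higher in every class compared, at 6.03 (5.81 to 6.26) in endothelial-like cells. Loss of Runx1 in Cx3cr1-expressing cells alone cannot be told apart from other origins by this value, because the endothelial-like cells were collected by the same Cx3cr1 reporter. Free RNA from endothelial, pericyte or erythrocyte-like cells would bring its markers along, but Vps8 in microglia-like cells was at 3.74 times the most that any of these would bring. Of the 12 genes higher in 3 classes, 1 lay on chromosome 16 with Runx1, where 0.41 would be expected from the genes measured. A count this small cannot show an excess or a shortfall. The other genes lay off chromosome 16, so their own position does not link them to DNA inherited with the floxed allele. The gene on chromosome 16 was Vps8 itself, 71.2 Mb from Runx1, for which such inheritance stays open. With the background taken out, 5 of the 12 were still at least 2-fold higher in all 3 classes, and since that removal rests on an assumed profile, free RNA cannot be told apart from other sources for the set as a whole; tamoxifen, an effect of microglia on other cells and differences between the libraries stay open as untested.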
